A study of Mus musculus with 29 samples.

How the data were processed

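MicroRNAs (miRNAs), short RNAs that repress the messenger RNAs they pair with, were sequenced in the tibialis anterior muscle, a fast-twitch muscle of the lower leg, and in the serum of C57BL/6 mice. The samples are 29 libraries in 6 groups: young, old and disuse muscle with 5 libraries each, young and disuse serum with 5 each, and old serum with 4. Per the labels, young mice were 6 months old, old mice 24 months, and disuse mice 6 months with muscle wasting induced by disuse. The way disuse was imposed and its duration are not given in the sources used here. Numbered samples are taken as separate samples of a group. No label states that each comes from a separate animal, so p-values measure the spread between these samples, which may be partly technical. The labels do not say whether muscle and serum came from the same animals.

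Per the labels' protocols, muscle RNA was extracted with Trizol and serum RNA was purified from 300 µl with a serum and plasma kit. Libraries were made with the TruSeq small RNA kit from 2 µg of muscle RNA or 10 ng of serum RNA, amplified for at most 15 PCR cycles and size-selected on a gel between 145 and 160 bp. Extraction and input therefore differ between the sources in the same way in every library. Bowtie and the mouse build mm10 were used per the submitters' processing notes. The Bowtie version, the miRNA annotation and the rule for reads that match several miRNAs are not given in the sources used here.

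The authors deposited a single table of counts, whole numbers of reads per mature miRNA and library, with no normalization. It holds 1183 miRNAs. For 695 of them there is a value for each of the 29 libraries. The other 488 have 28 values, of which the leading 13 are 0 and the last 15 are not all 0. In those 488, the totals of the last 15 values followed muscle depth when aligned to the right end of the header (r = 0.957 across libraries on a log scale) and not when read from the left (r = -0.17). Only the 695 complete miRNAs were used, and the right-aligned reading was kept as an alternative with serum set to 0. The 488 hold 17450 counts, or 0.0518% of muscle counts. Because those miRNAs have no cell in the last column of the deposited table, that column's unit was recorded as other, and its values in the complete miRNAs are counts. All 29 columns matched a sample by title, and 0 columns lacked one. No miRNA name was duplicated.

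Total counts per library were 254624 to 5943445 in muscle and 45176 to 309133 in serum. A count of 0 allows an abundance of up to 3 counts of the library total, which is 0.505 to 11.8 CPM (counts scaled by the library total) in muscle and 9.71 to 66.4 CPM in serum. Such limits cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Every pair of libraries within a group differed beyond counting noise: over 56 pairs the chi-square per degree of freedom was at least 15.7, with a median of 87.4. Amplified libraries of a single sample would exceed counting noise too, so this does not show that they are separate samples. Each library was counted as a sample because the labels number it as one.

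Differences were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with TMM factors, the filterByExpr filter by group and Benjamini-Hochberg adjustment. A miRNA passed at an adjusted p under 0.05. The 15 muscle libraries were fitted together and so were the 14 serum libraries, so that 3 groups share an estimate of the spread. Young serum was compared with young muscle over the 10 young libraries. The difference of a change between serum and muscle was tested as an interaction over all 29 libraries. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. CPM are given with the SD over libraries and are scaled by the TMM factors of each fit, so the same group can have other CPM in another fit. Small biases of composition remain: other scalings moved the median log2 fold change of all tested miRNAs, which was -0.01 for old against young muscle and -0.21 with upper-quartile factors. For disuse against young muscle it was -0.19 with those factors. For young serum against young muscle it was -0.34, against 0.17 with library totals and -0.13 with DESeq2's factors. For the age interaction it was -0.06, against -0.23 with library totals.

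Groups of miRNAs were 18 lists: muscle miRNAs (myomiRs), the Dlk1-Dio3 imprinted cluster, the let-7 and miR-98, miR-29, miR-30, miR-181, and miR-34 and miR-449 families, the miR-17-92 cluster and its paralogues, the miR-23-27-24 clusters, miR-221 and miR-222, inflammation-associated miRNAs, and miRNAs of erythrocytes, leukocytes, endothelium, fibroblasts and smooth muscle, liver, neural tissue, and epithelium and pancreas. Several miRNAs stand in more than a single list. miR-486-5p and miR-3107-5p are muscle and erythrocyte miRNAs, miR-34a-5p and miR-155-5p are also inflammation-associated, and miR-25-3p and miR-92a-3p are in the erythrocyte and the miR-17-92 lists. Most cell-type miRNAs are also detected in whole muscle, which itself contains several of these cell types. How specific such a list is to its cell was not tested. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of at least 2 tested members within a comparison. Members past the threshold were counted over all tested miRNAs and also adjusted over the list alone. Of 19 list calls, 2 held with an estimated correlation, both of the Dlk1-Dio3 cluster in old muscle. Shares of counts and the ratio of miR-451a to miR-23a-3p, a common index of red cell lysis in serum, were compared by exact two-sided permutation tests in a family of 20.

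The names printed were chosen by a rule. For old and for disuse against young in each source, these are the 10 largest rises and 10 largest falls among the miRNAs that passed with a mean of at least 10 CPM over the 2 groups. Where fewer than 10 passed, the smallest unadjusted p-values were added up to 10, as values. In every comparison the measured muscle miRNAs were added, and up to 4 members of each other list by smallest unadjusted p. For serum against muscle these are also the 10 most abundant of each source and the 5 largest changes each way, and for other contrasts the 5 smallest p. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives covered scaling (library totals, DESeq2's and upper-quartile factors), filters, a fold threshold, the libraries in the fit, DESeq2 1.42.0, limma-voom, the replicate number as a block, abundant or erythrocyte miRNAs left out, and each library left out in turn. Chosen after seeing the data were the right-aligned reading, the fits without the shallowest libraries, the thinning of every library to the shallowest depth and the red cell ratio as a covariate. Bounds that would exclude an explanation were written before its test, except for cell types. After the values were seen, a margin of the error of the value was required in addition, the bound for the position in the cluster was replaced and the test of cell types was redefined. Together these turned 5 exclusions into open outcomes.

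The tests were tried on simulated counts with the real means, depths and spread, in 10 sets per comparison. For old against young muscle, with 60 of 341 miRNAs changed, 26.0% of changes of 1.5-fold, 70.0% of 2-fold and 98.5% of 4-fold were found, and 3.47% of calls were false. For disuse against young muscle these were 19.5%, 63.0%, 97.0% and 3.75%. With 30 of 165 changed they were 5.00%, 44.0%, 88.0% and 6.16% for old serum, and 7.00%, 42.0%, 94.0% and 5.30% for disuse serum. For the age interaction, with 30 of 241 changed, they were 2.00%, 18.0%, 58.0% and 3.70%.

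Loci are from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, matched by miRNA gene name. Of 1183 miRNAs, 1103 matched a single annotated gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.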

Results

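Small RNA was sequenced from the tibialis anterior muscle and the serum of young, old and disuse mice to profile miRNAs in muscle wasting that comes with age and in wasting that is induced. Each group had 5 libraries except old serum, which had 4. Muscle libraries held a median of 2169800 counts and serum libraries a median of 170854. In muscle the group medians were 535754 counts for young, 2825032 for old and 2298437 for disuse, so the young libraries were shallower. The shallowest muscle libraries were disuse muscle 3 with 254624 counts and young muscle 1 with 268350. In serum the medians were 133658, 128297 and 174378 counts, and old serum 4 was the shallowest with 45176. Between 368 and 546 miRNAs were detected per muscle library and between 229 and 425 per serum library. A single miRNA, miR-133a-3p, an abundant miRNA of striated muscle, took 43.2% ± 4.61 (SD, n = 5) of the counts of young muscle. miR-486-5p, which is made in muscle and in red cell precursors, took 24.3% ± 6.49 (SD, n = 5) of those of young serum.

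The comparison of old with young muscle asks which miRNAs differ between 24 and 6 months of age. Old muscle had less of a block of miRNAs from the Dlk1-Dio3 domain, an imprinted region whose many miRNAs are expressed from the maternal chromosome. miR-127-3p fell from 6628 ± 1225 to 2404 ± 573 CPM (SD, n = 5 each), a log2 fold change of -1.46 ± 0.19 (SE). miR-434-3p fell from 406 ± 93.8 to 123 ± 30.4 CPM (log2 fold change -1.71 ± 0.21). miR-381-3p fell from 46.6 ± 13.7 to 10.3 ± 5.05 CPM (log2 fold change -2.14 ± 0.29). The increases were fewer, and miR-29a-3p, of a family that targets collagen messenger RNAs, rose from 2219 ± 249 to 3744 ± 519 CPM (log2 fold change 0.75 ± 0.16).

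**Figure D1:**
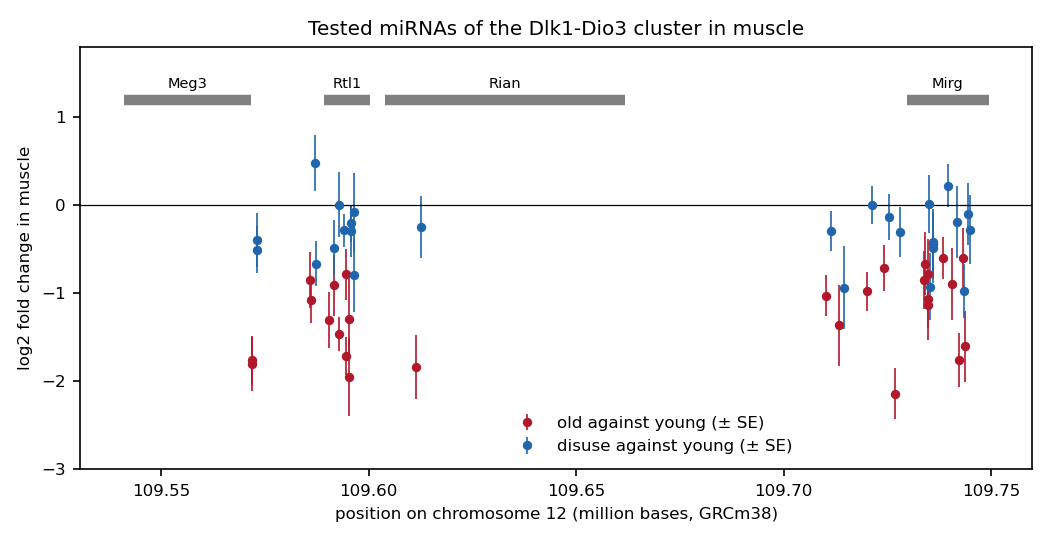
Log2 fold change against young muscle (vertical axis, bars ± SE) of the 27 tested miRNAs of the Dlk1-Dio3 cluster, placed by hairpin position on chromosome 12 of GRCm38 (horizontal axis), with disuse points shifted slightly to the right for legibility and gray bars for the genes Meg3, Rtl1, Rian and Mirg. All 27 old muscle points lie below 0, between -2.14 and -0.60, and none of the disuse points passed the test.

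Of all tested miRNAs, 20 passed between old and young muscle in edgeR's quasi-likelihood test, 4 higher and 16 lower. In all, 73 had an unadjusted p under 0.05, where chance gives 17.05. All the named miRNAs that passed lay beyond the young median in 5 of 5 old libraries. In the Dlk1-Dio3 cluster, 0 members rose, 13 of 27 tested members fell and 14 did not pass; adjusted over the list alone, 24 fell. The median log2 fold change was -1.08, with camera adjusted p = 9.44e-28 and adjusted p = 0.00168 with an estimated correlation. Besides miR-434-3p (adjusted p = 1.39e-05), miR-127-3p (1.79e-05) and miR-381-3p (1.84e-05), the named members that fell were miR-673-5p (-1.80), miR-673-3p (-1.76), miR-541-5p (-1.76), miR-431-5p (-1.30), miR-540-3p (-1.08) and miR-411-5p (-1.03). Their adjusted p-values were 9.39e-05 to 0.00969. Of the lower miRNAs outside the cluster, miR-455-3p, which lies in an intron of the collagen gene Col27a1, fell from 28.96 ± 21.3 to 8.37 ± 3.29 CPM (log2 fold change -1.96 ± 0.37, adjusted p = 0.00118). let-7d-3p fell from 2428 ± 469 to 1626 ± 277 CPM (-0.58 ± 0.17, adjusted p = 0.0387).

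The 4 miRNAs that rose were miR-342-3p (1.17 ± 0.27, adjusted p = 0.00679), miR-92a-1-5p (0.88 ± 0.24, 0.0263), miR-138-5p (0.79 ± 0.22, 0.0249) and miR-29a-3p (adjusted p = 0.00294). miR-342-3p, abundant in lymphocytes, reached 553 ± 293 CPM in old muscle against 246 ± 61.5 CPM in young. In the miR-29 family 1 of 7 tested members rose and 6 did not pass; adjusted over the list alone, 3 rose. The family's median was 0.58 with camera adjusted p = 0.00122, and adjusted p = 0.173 with an estimated correlation. Its other members had values of 1.15 (miR-29b-2-5p, adjusted p = 0.0666), 0.67 (miR-29b-3p) and 0.58 (miR-29c-3p). In the leukocyte list, miR-342-3p rose and the other 5 tested members did not pass, among them miR-223-3p at 0.85 and miR-142-3p at 0.52 (median 0.46, camera adjusted p = 0.0907). In the miR-17-92 list, miR-92a-1-5p rose and 13 did not pass, with miR-18a-3p at 0.70 (median 0.24, camera adjusted p = 0.167). In the let-7 list, let-7d-3p fell and 16 did not pass (median -0.08, camera adjusted p = 0.528).

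None of the 9 tested muscle miRNAs passed between old and young muscle; adjusted over the list alone, 2 fell (median -0.46, camera adjusted p = 0.667). miR-133a-3p was at 456970 ± 89222 CPM in old and 427210 ± 66535 CPM in young muscle, a log2 fold change of 0.10 ± 0.14. miR-486-5p had a value of -0.50 (adjusted p = 0.0783), miR-3107-5p -0.46, miR-133a-5p -0.60, miR-1a-3p -0.52, miR-208b-3p -0.50, miR-499-5p 0.45, miR-133b-3p 0.38 and miR-206-3p, a miRNA of regenerating fibres, 0.21. miR-1a-3p, a miRNA of all striated muscle, was counted at 645 ± 122 CPM in old and 927 ± 357 CPM in young muscle. The remaining lists had 0 members past the threshold and no camera call. Their medians and camera adjusted p-values were 0.25 and 0.308 for the 11 tested members of the miR-30 family, -0.33 and 0.319 for the 7 of miR-181 (adjusted over the list alone, 1 fell), and 0.59 and 0.289 for the 2 of miR-34 and miR-449 (adjusted over the list alone, 1 rose). They were 0.17 and 0.528 for miR-23-27-24, 0.47 and 0.528 for miR-221 and miR-222 (adjusted over the list alone, 2 rose and 1 fell), 0.22 and 0.251 for the inflammation-associated miRNAs, and -0.08 and 0.704 for the erythrocyte list (adjusted over the list alone, 2 fell). They were -0.35 and 0.667 for the endothelial list (adjusted over the list alone, 1 fell), 0.07 and 0.784 for fibroblasts and smooth muscle, -0.02 and 0.979 for liver, and 0.42 and 0.336 for neural miRNAs; the single tested epithelial member, miR-203-3p, was at -0.17. With upper-quartile factors, which lower the median of all miRNAs to -0.21, 36 passed (2 higher, 34 lower), and with every library thinned to the shallowest depth 9 did. Some calls were lost when a single library was left out, while their log2 fold changes kept their sign. miR-138-5p did not pass without old muscle 1 (0.68, adjusted p = 0.0720) or young muscle 5 (0.76, 0.0531). miR-92a-1-5p did not pass without old muscle 1 (0.83, 0.0607), nor miR-431-5p without young muscle 5 (-1.06, 0.0629). let-7d-3p did not pass without any of old muscle 1 to 4 and young muscle 1 to 4 (-0.55 to -0.39, adjusted p = 0.0746 to 0.201).

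**Figure D2:**
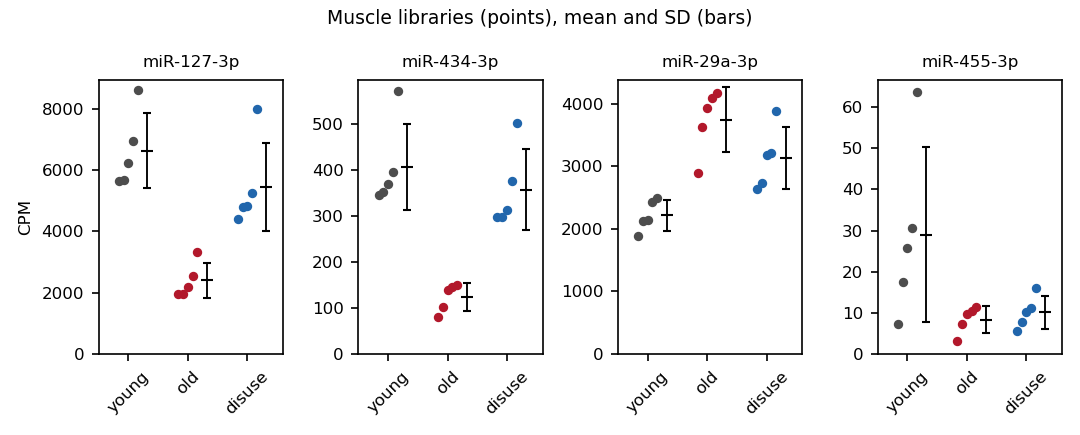
CPM of named miRNAs in each young, old and disuse muscle library (points, sorted within a group; vertical axes in CPM), with bars for the mean and SD of the 5 libraries of a group. miR-127-3p and miR-434-3p are lower in every old library than in every young library, and miR-455-3p is lower in old and in disuse muscle on average.

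The comparison of disuse with young muscle asks which miRNAs differ when wasting is induced at the same age of 6 months. A single miRNA passed: miR-455-3p fell from 28.96 ± 21.3 to 10.1 ± 3.94 CPM (SD, n = 5 each), a log2 fold change of -1.83 ± 0.39 (adjusted p = 0.0336), and was below the young median in 5 of 5 disuse libraries. Of all tested miRNAs, 29 had an unadjusted p under 0.05, where chance gives 17.05. The next smallest p-values, none past the threshold, were those of miR-92a-1-5p (1.03 ± 0.25, adjusted p = 0.0652; 22.2 ± 1.26 against 10.1 ± 2.89 CPM), miR-6240 (-1.24 ± 0.31, 0.0712), miR-222-3p (0.72, 0.182), miR-214-3p, a fibroblast miRNA (0.63, 0.192), miR-541-5p (-0.97, 0.209) and miR-29a-3p (0.50, 0.209). They were followed by miR-149-5p at 0.46, miR-18a-3p at 0.79 and miR-133a-5p at -0.85. The muscle miRNAs had values of 0.22 (miR-133a-3p), 0.48 (miR-133b-3p), 0.26 (miR-499-5p), -0.33 (miR-1a-3p), -0.15 (miR-486-5p), -0.15 (miR-3107-5p), -0.19 (miR-206-3p) and -0.21 (miR-208b-3p), and 0 of 9 passed (camera adjusted p = 0.672).

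In the Dlk1-Dio3 cluster 0 of 27 members passed between disuse and young muscle, also adjusted over the list alone. The cluster's median was -0.29 with camera adjusted p = 0.0132, a call lost at adjusted p = 0.727 with an estimated correlation. No other list passed, and 0 members of any passed. Camera adjusted p-values were 0.183 for miR-17-92 (adjusted over the list alone, 2 rose), 0.267 for miR-29 (1 rose), 0.552 for miR-30, 0.663 for miR-221 and miR-222 (1 rose), 0.663 for the endothelial list and 0.672 for fibroblasts and smooth muscle (1 rose). They were 0.672 for leukocyte, liver, neural and miR-181 miRNAs, 0.688 for the inflammation-associated and the miR-34 and miR-449 lists, 0.728 for let-7, 0.982 for miR-23-27-24 and 0.996 for the erythrocyte list. The call of miR-455-3p was lost in limma-voom and with a filter of 10 CPM, in the thinned libraries 0 miRNAs passed, and the call was also lost without young muscle 3 (adjusted p = 0.0571) or 5 (0.164) or disuse muscle 1 (0.136), 2 (0.0917), 4 (0.102) or 5 (0.157); without young muscle 2, 2 miRNAs passed.

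Old muscle was also set directly against disuse muscle. These groups differ in age (24 against 6 months) as well as in disuse, so the 2 cannot be told apart here. The Dlk1-Dio3 miRNAs were lower in old muscle here too, with the same 5 old libraries as in the comparison with young muscle. miR-434-3p was at 123 ± 30.4 CPM in old and 357 ± 86.9 CPM in disuse muscle (n = 5 each), a log2 fold change of -1.51 ± 0.21 (adjusted p = 1.03e-04). miR-127-3p was at 2404 ± 573 against 5445 ± 1446 CPM (-1.18 ± 0.19, adjusted p = 3.30e-04), and miR-381-3p had a log2 fold change of -1.84 ± 0.29 (adjusted p = 2.40e-04). Of the miRNAs tested, 12 passed, 2 higher and 10 lower in old muscle, and 48 had an unadjusted p under 0.05. The cluster held 9 of the 10, with 18 members not passing; adjusted over the list alone, 18 fell. Its median was -0.82 (camera adjusted p = 2.12e-23, and adjusted p = 9.08e-04 with an estimated correlation). miR-673-3p (-1.26) and miR-667-3p (-0.98) were also lower, both with adjusted p = 0.00685. Outside the cluster let-7d-3p was lower (-0.72 ± 0.17, adjusted p = 0.0111). The 2 higher miRNAs were miR-34a-5p, a target of the tumour suppressor p53, at 120 ± 36.4 against 63.6 ± 17.1 CPM (0.88 ± 0.24, adjusted p = 0.0348), and miR-6240 (1.18 ± 0.29, adjusted p = 0.0158), which was named after its values were seen.

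Between old and disuse muscle, 5 further lists passed camera, all higher in old muscle and all lost with an estimated correlation. The miR-29 list (0 members past the threshold, median 0.44) had adjusted p = 0.0154 and adjusted p = 0.170 with an estimated correlation. The miR-30 list (0 members, median 0.21) also had 0.0154, and adjusted p = 0.205 with an estimated correlation. The miR-34 and miR-449 list (1 of 2 rose, median 0.67), the inflammation-associated list (1 of 8 rose, median 0.33) and the neural list (0 of 2; adjusted over the list alone, 1 rose; median 0.60) each had 0.0434, and adjusted p = 0.130 with an estimated correlation. In both of the lists with a member that rose, it was miR-34a-5p. The miRNAs that did not hold without a single library were miR-34a-5p (without old muscle 4 or 5 or disuse muscle 2, 3, 4 or 5, adjusted p = 0.0601 to 0.101), let-7d-3p (without old muscle 2 or 4 or disuse muscle 3 or 4, 0.0687 to 0.0840) and miR-667-3p (without disuse muscle 4, 0.0528). The total was 8 without disuse muscle 4.

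The changes of old and of disuse muscle against young muscle correlated across the tested miRNAs with r = 0.60 and rho = 0.60. Both use the same 5 young libraries. Sets with every library simulated as unchanged, and the simulated young libraries shared, gave r = 0.576 on average (SD 0.0452, 50 simulations). Each miRNA was drawn independently there, so features of the real young libraries common to many miRNAs are not reproduced. miRNAs are not independent replicates, so no p-value is attached. The covariance was 0.128 against a simulated 0.0576, and with the young libraries split between the comparisons the median r over 20 splits was 0.147 (-0.00588 to 0.297) with a covariance of 0.0628. At the threshold, 1 miRNA, miR-455-3p, was called in both and in the same direction, where independent lists would share 0.0469. At an unadjusted p under 0.05, 15 were shared (9 up, 6 down), against 3.80 simulated, 1.19 up and 1.94 down for independent lists, and a median of 7.50 with split young libraries.

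The comparison of old with young serum asks the same of circulating miRNAs. Old serum had more miR-146a-5p, a regulator of innate immune signalling, at 49285 ± 11940 CPM (n = 4) against 21286 ± 6958 CPM (n = 5), a log2 fold change of 1.21 ± 0.30. miR-192-5p and miR-215-5p, related miRNAs of liver, gut and kidney, rose by 1.10 ± 0.26 and 0.97 ± 0.25 on the log2 scale. miR-127-3p, of the Dlk1-Dio3 cluster, fell from 1456 ± 336 to 434.2 ± 151 CPM (-1.78 ± 0.31). miR-144-5p and miR-451a, which are processed from a shared transcript of red cell precursors, fell by 2.16 ± 0.48 and 0.82 ± 0.24.

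Of 165 tested miRNAs, 16 passed between old and young serum, 4 higher and 12 lower, and 38 had an unadjusted p under 0.05, where chance gives 8.25. All 16 lay beyond the young median in 4 of 4 old libraries. The fourth increase was miR-423-3p (0.74 ± 0.23, adjusted p = 0.0472), beside miR-192-5p (0.0173), miR-146a-5p (0.0184) and miR-215-5p (0.0187). The smallest adjusted p-value was that of miR-127-3p (0.00306). The other falls were miR-211-5p (-3.53 ± 0.81, adjusted p = 0.0159; 10 counts in all old libraries against 173 in young; -2.19 without young serum 1, -4.43 without old serum 3), miR-151-5p (-1.58), miR-98-5p (-1.40), miR-15b-5p (-1.29), let-7f-5p (-1.27), miR-181b-5p (-1.12), miR-148b-3p (-1.11), miR-26a-5p (-0.96) and miR-181a-5p (-0.85). Their adjusted p-values were 0.0154 to 0.0465.

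**Figure D3:**
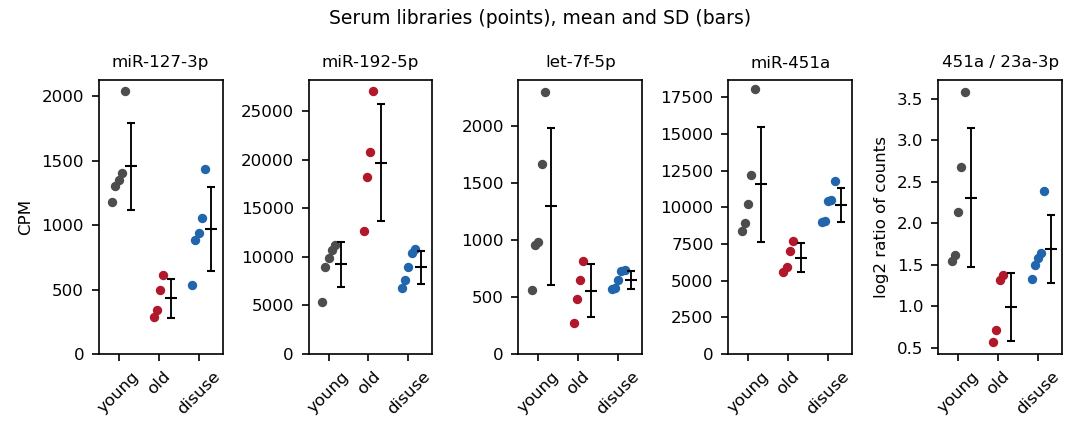
CPM of named miRNAs in each young, old and disuse serum library (points, sorted within a group; vertical axes in CPM), and in the last panel the log2 ratio of miR-451a to miR-23a-3p, with bars for the mean and SD (n = 5, 4 and 5). The 4 old libraries lie above the young median for miR-192-5p and below it for miR-127-3p and let-7f-5p, and the ratio is 0.99 ± 0.41 in old against 2.31 ± 0.84 in young serum.

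In the let-7 and miR-98 list, 2 of 11 tested members fell and 9 did not pass; adjusted over the list alone, 5 fell (median -0.81, camera adjusted p = 0.0276, and adjusted p = 0.429 with an estimated correlation). let-7d-5p (-1.08, adjusted p = 0.0508) and let-7a-5p (-1.02, 0.0587) were among those that did not pass. In the miR-181 family 2 of 4 fell; adjusted over the list alone, 3 fell (median -0.77, camera adjusted p = 0.0276, and adjusted p = 0.429 with an estimated correlation). In the Dlk1-Dio3 list 1 of 2 fell and miR-434-3p was at -1.40 (adjusted p = 0.0571); adjusted over the list alone, 2 fell (camera adjusted p = 0.0221, and adjusted p = 0.229 with an estimated correlation). In the erythrocyte list 2 of 9 fell and 7 did not pass; adjusted over the list alone, 3 fell (median -0.37, camera adjusted p = 0.0552). The ratio of miR-451a to miR-23a-3p was 0.99 ± 0.41 (SD, n = 4) on the log2 scale in old serum and 2.31 ± 0.84 (n = 5) in young serum (exact permutation p = 0.0238, adjusted p = 0.381 over 20 tests).

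The muscle miRNAs tested in serum did not pass between old and young: miR-133a-3p was at -0.05, miR-133a-5p at 0.29, miR-486-5p at -0.31 and miR-3107-5p at -0.30 (0 of 4, camera adjusted p = 0.974). miR-146a-5p was the member that rose of 6 inflammation-associated miRNAs (camera adjusted p = 0.347) and miR-192-5p that of 4 liver miRNAs (0.578), where miR-122-5p, the main miRNA of hepatocytes, was at 0.09. Lists with 0 members past the threshold were miR-29 (camera adjusted p = 0.347; adjusted over the list alone, 1 rose), miR-30 (0.631), miR-17-92 (0.915), miR-23-27-24 (0.280), miR-221 and miR-222 (0.655), leukocyte (0.655), endothelial (0.631), fibroblast and smooth muscle (0.773), and epithelial and pancreatic miRNAs (0.356). No miR-34 or miR-449 member and no neural member was tested in serum. These serum calls depended on single libraries and settings: without old serum 2 miR-127-3p alone passed (adjusted p = 0.0264), without old serum 1 9 miRNAs passed, with library totals 5 did (2 higher, 3 lower), and with the ratio of miR-451a to miR-23a-3p as a covariate 0 did.

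Between disuse and young serum 0 of 165 miRNAs passed in edgeR's test (smallest adjusted p = 0.358), 20 had an unadjusted p under 0.05, where chance gives 8.25, and 0 passed in DESeq2 and in limma-voom. Without a filter on low counts 5 passed. Simulated 2-fold changes were found in 42.0% of cases here, so changes of that size could be missed at this depth. The smallest p-values were those of miR-6240 (-3.12 ± 0.97; 29.6 ± 24.3 against 276 ± 526 CPM, with young serum 4 at 1216 CPM and the other young libraries at 29.2 to 66.9, and 3 of 5 disuse libraries below the young median), let-7f-5p (-0.99 ± 0.33; 652 ± 78.2 against 1292 ± 689 CPM, n = 5 each), miR-98-5p (-0.89), miR-214-3p (0.92), let-7a-5p (-0.85), miR-223-3p, a myeloid cell miRNA (0.63), miR-128-3p (-1.04, with young serum 4 at 1836 CPM and the other young libraries at 342 to 529), miR-181a-5p (-0.52), miR-204-5p (-0.84) and let-7i-5p (-0.63). miR-127-3p was at -0.58, miR-451a at -0.19, miR-133a-3p at 0.01 and miR-486-5p at -0.12. Of the lists, let-7 (0 of 11 past the threshold; adjusted over the list alone, 3 fell; median -0.59) had camera adjusted p = 0.00450, and adjusted p = 0.444 with an estimated correlation. The miR-181 family (0 of 4; adjusted over the list alone, 4 fell; median -0.62) had 0.00490, and also adjusted p = 0.444 with an estimated correlation. The other lists had camera adjusted p-values of at least 0.182.

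Between old and disuse serum 4 of 165 miRNAs passed and 17 had an unadjusted p under 0.05. miR-192-5p (1.14 ± 0.26), miR-215-5p (1.04 ± 0.25) and miR-146a-5p (1.28 ± 0.30) were higher in old serum, each with adjusted p = 0.0304 and in 4 of 4 old libraries. miR-127-3p was lower, at 434.2 ± 151 (n = 4) against 970 ± 326 CPM (n = 5; -1.20 ± 0.30, adjusted p = 0.0383). miR-144-5p was at -1.67 (adjusted p = 0.0883). No list passed (Dlk1-Dio3 camera adjusted p = 0.0509). With library totals, with a filter of 10 CPM and with the red cell ratio as a covariate 0 passed. The same held without old serum 1, 2 or 3 or disuse serum 3, 4 or 5, and 1 passed without disuse serum 2.

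The changes of old and of disuse serum against young serum correlated across the 165 miRNAs with r = 0.70 and rho = 0.67. Sets with every library simulated as unchanged, and the simulated young libraries shared, gave 0.467 (SD 0.0603). As in muscle, features of the real young libraries common to many miRNAs are not reproduced there. The covariance was 0.232 against 0.0718, and with split young libraries the median r was 0.183 (-0.0531 to 0.365) with a covariance of 0.0692. No miRNA was called in both, since 0 were called in disuse serum. At an unadjusted p under 0.05, 14 were shared, 3 up (miR-145a-5p, miR-223-3p and miR-93-3p, named after their values were seen) and 11 down. Simulated groups shared 1.84, independent lists 0.364 up and 2.23 down, and split young libraries a median of 5.50.

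Young serum and young muscle were compared, over the miRNAs with a value for every library, to see which miRNAs make up each source. Muscle was dominated by miR-133a-3p, at 537650 ± 186410 CPM against 1963 ± 782 CPM in serum (n = 5 each; log2 fold change -8.10 ± 0.47, adjusted p = 4.33e-12). Serum was rich in miR-486-5p (221890 ± 109760 CPM), miR-10b-5p (74300 ± 43760 CPM) and miR-191-5p (65633 ± 38319 CPM). miRNAs of epithelia were found in serum and hardly in muscle. miR-205-5p, of stratified epithelium, had 2097 counts in serum and 4 in muscle (11.09 ± 0.52, adjusted p = 4.95e-13). miR-429-3p had 413 counts in serum and 0 in muscle, at least 1086-fold higher, taking 3 counts over the group as the limit of 0. miR-143-5p had 398 counts in muscle and 0 in serum, at least 16.8-fold lower in serum by the same limit. Both bounds use raw group totals without the TMM factors, so they are not on the scale of the fitted changes.

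Of 190 tested miRNAs, 145 passed, 62 higher and 83 lower in serum, and 148 had an unadjusted p under 0.05. The miRNAs left out because they lack a value are not among those tested. Aligned to the right end of the header, they have counts in muscle and none in serum. miR-208a-5p, for example, then has 1079 counts in young muscle. The count of miRNAs lower in serum therefore leaves out miRNAs found in muscle alone by that reading. With library totals, which move the median of all miRNAs from -0.34 to 0.17, 76 were higher and 68 lower. All 8 epithelial and pancreatic members rose in serum, with a median of 9.67 (camera adjusted p = 4.32e-07, and adjusted p = 0.0766 with an estimated correlation). The median was 9.28 with the 2 members without muscle counts at their bound from raw totals. miR-141-3p was at 9.92 ± 0.57 (10.51 without young muscle 2, 9.31 without young muscle 5), and miR-200b-3p had 530 counts in serum and 2 in muscle. All 4 liver miRNAs rose, among them miR-122-5p (9.29 ± 0.79; 10.14 without young muscle 5) and miR-192-5p (6.99 ± 0.42), with a median of 5.76 (camera adjusted p = 0.00884, and adjusted p = 0.194 with an estimated correlation). In the erythrocyte list 8 of 9 rose, among them miR-451a (7.12 ± 0.48; 9647 ± 2903 against 69.4 ± 43.7 CPM), miR-16-5p (3.40) and miR-25-3p (3.40), and miR-92a-3p at -0.38 did not pass (median 3.40, camera adjusted p = 0.00884, and adjusted p = 0.471 with an estimated correlation). In the let-7 list 12 of 13 fell, with let-7a-5p at -5.20 ± 0.40 (median -2.95, camera adjusted p = 0.00790, and adjusted p = 0.643 with an estimated correlation).

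The other lists did not pass camera in serum against muscle. Of 7 muscle miRNAs, miR-133a-3p, miR-133b-3p (-6.81), miR-1a-3p (-6.28; -7.09 without young serum 3), miR-206-3p (-4.73) and miR-133a-5p (-2.75) fell, and miR-486-5p (1.44) and miR-3107-5p (1.57) rose (camera adjusted p = 0.180). All 5 tested Dlk1-Dio3 members were lower in serum, with miR-127-3p at -2.76 and miR-540-3p at -4.13, or -4.81 without young serum 2 (0.274). Of the leukocyte list 4 rose, with miR-142-5p at 7.52 and miR-223-3p at 5.41, and 2 fell, miR-150-5p (-3.28) and miR-155-5p (-5.74) (0.418). Of the inflammation-associated list 4 of 8 rose, with miR-146a-5p at 5.897 and miR-21a-5p at 3.54, and 3 fell (0.443). Of the fibroblast and smooth muscle list 1 of 8 rose and 6 fell, with miR-145a-5p at -5.98 (0.274). The counts risen and fallen were 2 and 5 of 9 for miR-30 (0.533), 2 and 3 of 5 for miR-181 (0.701), 4 and 0 of 5 for miR-17-92 (0.274), 3 and 2 of 6 for miR-23-27-24 (0.544), 1 and 0 of 2 for the endothelial list (0.533), 0 and 1 of 3 for miR-29 (0.702) and 0 of 2 for miR-221 and miR-222 (0.753). The single tested member of the miR-34 and of the neural list fell, miR-34a-5p by 2.87 and miR-338-3p by 1.42. The largest fall in serum was that of miR-196a-5p (-9.39 ± 0.54; -10.16 without young serum 3), a miRNA of the HOX gene clusters, and among the abundant miRNAs of muscle miR-378a-3p, which lies in the metabolic gene Ppargc1b, was at -5.12. Extraction and RNA input differ between the sources, so that source and protocol cannot be told apart.

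Whether a change differs between serum and muscle was tested as an interaction over 241 miRNAs. For age 2 passed, both lower in old serum relative to the change in muscle, and 34 had an unadjusted p under 0.05. miR-211-5p had a difference of -4.41 ± 0.92 (adjusted p = 0.00715; -3.39 without young serum 1, -5.29 without young muscle 5 and -5.51 without old serum 3), with a change of -3.53 in serum and 1.01 in muscle (adjusted p = 0.134 there). miR-15b-5p, a regulator of the cell cycle, had a difference of -1.60 ± 0.40 (adjusted p = 0.0391), with a change of -1.29 in serum and 0.43 in muscle. The next were miR-192-5p (1.25, adjusted p = 0.0753), miR-92b-3p (1.13, 0.0764) and let-7d-3p (1.09, 0.0764). No list passed (smallest camera adjusted p = 0.883). The count was 1 without young muscle 1, young serum 5 or old serum 2, 4 without old muscle 4, 5 without young serum 4 or old serum 3 or 4, 6 without young serum 1 and 9 without young muscle 5. miR-15b-5p did not pass without old serum 2 (adjusted p = 0.131), young muscle 1 (0.0878), young serum 4 (0.0631) or young serum 5 (0.0503).

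For disuse 0 of 241 miRNAs passed the interaction in edgeR's test (smallest adjusted p = 0.275, miR-205-5p at -2.89), and 24 had an unadjusted p under 0.05; the same count in limma-voom with sample quality weights was 0. The miR-30 list (0 of 10 past the threshold, median 0.46) had camera adjusted p = 0.0429, and adjusted p = 0.596 with an estimated correlation, and the other lists had at least 0.277. Without disuse muscle 2, 1 miRNA passed.

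The share of counts in abundant miRNAs was compared in 20 exact permutation tests, of which 0 passed (smallest adjusted p = 0.381). miR-133a-3p took 46.3% ± 5.68 of counts in old, 47.8% ± 1.64 in disuse and 43.2% ± 4.61 in young muscle (n = 5 each). miR-486-5p and miR-3107-5p together took 7.26% ± 1.18 in old, 8.59% ± 0.783 in disuse and 10.2% ± 2.44 in young muscle (old against young, exact permutation p = 0.0476 before adjustment). In serum this share was 30.2% ± 9.18 in old (n = 4), 36.2% ± 5.91 in disuse and 36.6% ± 9.70 in young. The erythrocyte list took 34.7%, 41.4% and 42.1% of serum counts.

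The main loci are given on GRCm38. The hairpin of mmu-miR-127-3p lies on chromosome 12 at 109592846 to 109592915, that of mmu-miR-434-3p at 109594506 to 109594599 and that of mmu-miR-431-5p at 109590447 to 109590537, all on the plus strand opposite to an exon of Rtl1. mmu-miR-381-3p lies at 109726822 to 109726896, with no overlapping gene, and mmu-miR-541-5p at 109742409 to 109742498, in an intron of Mirg. Outside the cluster, mmu-miR-455-3p lies on chromosome 4 at 63256851 to 63256932 in an intron of Col27a1, and mmu-miR-29a-3p on chromosome 6 at 31062660 to 31062747, with no overlapping gene. mmu-miR-342-3p lies on chromosome 12 at 108658620 to 108658718 in an intron of Evl. Of those changed in serum, mmu-miR-192-5p lies on chromosome 19 at 6264844 to 6264932, mmu-miR-451a on chromosome 11 at 78073170 to 78073241, mmu-miR-15b-5p on chromosome 3 at 69009772 to 69009835 in an intron of Smc4 and mmu-miR-211-5p on chromosome 7 at 64205806 to 64205911 in an intron of Trpm1. mmu-miR-486-5p (chromosome 8, 23142555 to 23142682) and mmu-miR-3107-5p (23142573 to 23142662, opposite strand) come from overlapping hairpins in an intron of Ank1 with near-identical mature sequences, so their reads can be shared and their separate levels are uncertain. Reads of closely related members of the let-7, miR-29, miR-30 and miR-181 families can likewise be shared between members, since the rule for such reads is not given in the sources used here.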

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

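The tests of cell-type lists, the thinning of libraries and the red cell ratio as a covariate were chosen only after the results they bear on were seen. 2 outcomes below were also decided by rules changed after their values were seen. The cell-type test was first made on the lowest of the 3 list medians, which at -0.35 lay just past the bound against a change of cell content. It was then made for each list apart, for endothelium at first on miR-126a-3p, wrongly taken for its more abundant member, and finally on the list medians with a margin of 1 SE. The same margin was added for miR-455-3p in thinned libraries, whose value by the bound as first set would exclude depth. These changes left open a lower share of endothelial cells and, for miR-455-3p, depth. For 195 groups of values (library totals, shares of counts, and the CPM of the muscle miRNAs and of those past the threshold within a source) the highest or lowest library was compared with its neighbour by Dixon's criterion, which chance exceeds in about 1 in 20 groups, or 9.75 here. It was exceeded 21 times, and 5 times each in disuse muscle 3, old muscle 5 and young serum 1. Over the CPM of all named miRNAs, tried later, 43 of 729 groups exceeded it, where chance gives 36.5, so the excess is small there.

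Disuse muscle 3, the shallowest muscle library, stood above the others of its group in 5 miRNAs of the first set of values. It had 7978 CPM of miR-127-3p (others 4412 to 5237), 64.1 CPM of miR-381-3p (32.2 to 40.6), 36.1 CPM of miR-341-3p (9.22 to 13.1) and 24.1 CPM of miR-410-3p (5.60 to 10.7). It also had 192 CPM of miR-133a-5p (78.6 to 110). Among all named miRNAs it was also high in miR-10b-5p (7084, others 2128 to 3148), miR-19b-3p (28.1, others 3.95 to 6.07) and miR-25-5p (52.1, others 19.97 to 27.1), and low in miR-24-2-5p (32.1, others 78.9 to 86.5) and miR-29b-2-5p (4.01, others 17.0 to 20.2). In disuse muscle 4, miR-337-5p was low at 23.3 CPM (35.02 to 36.1). Old muscle 5 was high in miR-486-5p (65100 CPM, others 42590 to 46070), miR-3107-5p (30460, others 19740 to 22350), miR-206-3p (221, others 115 to 143) and miR-673-3p (15.2, others 7.68 to 8.30), and low in miR-92a-1-5p (13.9, others 19.9 to 22.0). Old muscle 3 had 1060 CPM of miR-342-3p (others 304 to 500) and 74.7 CPM of miR-142-5p, also of the leukocyte list (others 22.2 to 34.3). Without it miR-342-3p still passed, at 0.82 (adjusted p = 0.0246). Young muscle 4 had 570 CPM of miR-434-3p (others 345 to 396).

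In serum, young serum 1 was low in miR-146a-5p (9266 CPM, others 21270 to 26030) and high in miR-127-3p (2038, others 1178 to 1405), miR-181a-5p (28710, others 17320 to 18550), miR-181b-5p (2909, others 1182 to 1330) and miR-211-5p (683, others 63.5 to 153.7). Young serum 4 had 2305 CPM of miR-151-5p (others 577 to 770), and disuse serum 4 had 939 CPM of it (others 309 to 489). Disuse serum 4 also had the largest total of its group, 309133 counts (others 128216 to 177129). The change with age differed between serum and muscle, by the interaction test, for miR-211-5p (-4.41) and miR-15b-5p (-1.60). Among the miRNAs left out because they lack a value, miR-208a-5p, from an intron of the heart myosin gene Myh6, had 7420 counts in the 15 muscle libraries when aligned to the right end of the header. Pooled over the libraries of a group this is 178 CPM in young, 258 CPM in old and 193 CPM in disuse muscle, and no difference was tested.

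The fall of the Dlk1-Dio3 cluster in old muscle was weighed against depth, composition, cell content and chance. In 1 of 100 splits of the old and young libraries, the real split, the cluster's median was as large in size (-1.08, highest other 0.914). A share of 0.01 is the smallest that 100 splits can give, and the cluster was weighed after its fall had been seen. Chance is therefore unlikely but not excluded. With the 5 most abundant miRNAs left out the cluster's median was -1.09. TMM factors already trim such miRNAs, so this value was largely fixed in advance. A few abundant miRNAs that took more counts would lower all others when scaled by library totals. With library totals the median log2 fold change of all tested miRNAs was 0.009, which argues against them. With all libraries thinned to 1 depth the median of the 10 of 27 members still tested was -1.48. Thinning draws reads at random and keeps each miRNA's expected share of its library. A fall was therefore largely fixed in advance, so thinning cannot decide about depth. Disuse muscle had a median depth near that of old muscle (2298437 against 2825032 counts), although disuse muscle 3 was shallow. The cluster was lower in old than in disuse muscle too (median -0.82), which argues against depth. The lists of fibroblasts and smooth muscle and of leukocytes had medians of 0.066 and 0.46 (0.34 to 0.82 for leukocytes with any library left out, and 0.48 without old muscle 3). Neither median fell. Members ranged from -0.37 to 0.68 for fibroblasts and smooth muscle and from 0.01 to 1.17 for leukocytes, all above the highest cluster member (-0.60). This argues against a lower share of these cells, so far as the lists follow their cells, which was not tested. A lower share of endothelial cells could not be told apart, since that list has 2 tested members, at -0.72 and 0.03 (median -0.35), and a lower output of the imprinted domain with age remains an open hypothesis.

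The calls between old and young serum were weighed against red cell RNA, depth and chance. Their number was seldom reached by regrouping: in 1 of 100 splits, the real split, 16 or more miRNAs passed. The highest other was 15, in a split that moved young serum 2 alone across, so chance is not excluded by a wide margin. After thinning, 13 of the 16 were still tested and 7 passed, and the median size of the change of the 13 was 0.996 of its value. Since thinning at random keeps expected shares, a change of like size was largely fixed in advance, so thinning cannot decide about depth. The group medians were close (133658 counts in young and 128297 in old serum) with overlapping ranges (68813 to 290818 and 45176 to 260729). This argues against a difference of depth between the groups as the source of these calls. With the ratio of miR-451a to miR-23a-3p as a covariate, the 14 called miRNAs outside the erythrocyte list kept their sign, but their median size fell to 0.516 of its value (from 1.17 to 0.60 on the log2 scale, with SE from 0.298 to 0.365), and 0 of all tested miRNAs passed. Of all 16 changes, 15 were smaller with the covariate (miR-148b-3p was not) and 16 had a larger SE, and since the ratio was itself lower in the old libraries (by -1.31 on the log2 scale, exact permutation p = 0.0238, adjusted p = 0.381), red cell RNA and age cannot be told apart here.

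The fall of miR-455-3p in old and in disuse muscle was weighed against shared young libraries and depth. Its young values were spread widely, from 7.29 CPM in young muscle 1 to 63.6 CPM in young muscle 5. With the young libraries split between the comparisons, the weaker of the 2 changes reached -0.65 in the least favourable of 20 assignments, which leaves shared controls open. With thinned libraries that change was -1.39 (SE 0.536), with 0 to 17 counts per library, below the bound of -0.9 set beforehand but within the later margin of 1 SE, so depth also could not be told apart. An effect of muscle wasting, common to age and disuse, may add to it and is untested.

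Regrouping also seldom reached the counts of old against disuse muscle (12, highest other 1), old against disuse serum (4, highest other 2), serum against muscle (145, highest other 0) and old against young muscle (20, highest other 14). In each of these the real split alone, 1 of 100, gave as many. Chance could not be excluded for disuse against young muscle (1, highest other 7), where 11 of 100 splits gave as many. For the age interaction (2, highest other 14), 9 of 100 did. Its splits relabel age within each source, so age changes within a source can themselves give calls. They cannot decide about chance there. In both comparisons the highest split called several times the real count, and what lies behind it was not tested. Of the other splits, 89 and 82 made no call. The disuse split with 7 calls set disuse muscle 1 and 3 and young muscle 1, 3 and 4 apart, and 4 of these 5 have the fewest counts of the 10 libraries (254624 to 535754). For disuse against young serum (0, highest other 1) and the disuse interaction (0, highest other 2) all 100 splits gave as many.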

How the results depend on the processing

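The aligned short rows, the fits without shallow libraries, the thinning and the covariate were chosen after seeing the data. Where a count moved, the cause was not tested beyond the sizes and errors given above for the covariate. Old against young muscle (20) gave 36 with upper-quartile factors, 9 thinned and 17 to 27 with a library left out. Disuse against young muscle (1) gave 2 with upper-quartile factors, without a filter, with the 2 groups only and with the short rows aligned, 0 in limma-voom, with a 10 CPM filter and thinned, and 0 to 2 with a library left out. Old against disuse muscle (12) gave 8 (without disuse muscle 4) to 18 (without old muscle 1). Old against young serum (16) gave 5 with library totals, 7 with a 10 CPM filter, 6 with the 2 groups only, 7 thinned, 0 with the covariate, and 1 (without old serum 2) to 20 (without young serum 2). Disuse against young serum (0) gave 5 without a filter and 0 with any library left out. Old against disuse serum (4) gave 0 with library totals, a 10 CPM filter or the covariate, and 0 to 3 with a library left out. Serum against muscle (145) gave 270 without a filter, where more miRNAs are tested, and 147 to 156. The age interaction (2) gave 1 with quality weights, 0 with a 10 CPM filter in each source, 1 without shallow libraries and 1 to 9 with a library left out; the disuse interaction (0) gave 0 to 1. The 19 list calls became 2 with an estimated correlation and 12 with library totals. The fry test gave 33, but it asks whether a list changed at all and not whether it changed relative to the other miRNAs. The shared calls were 15 (muscle, from 1) and 14 (serum, from 0) at unadjusted p, and with split young libraries a median of 0 (0 to 1 over 20 splits) in each source. Apart from these and the replicate block, the alternatives left these counts within 1.5 times. DESeq2 gave 28, 1 and 14 in muscle, 21, 0 and 6 in serum. Of 114 calls of named miRNAs, 75 held under all their alternatives and 0 reversed. Most of the 75 were of serum against muscle, where 61 of 69 held. In muscle 9 of 15 held for old against young, 4 of 7 for old against disuse and 0 of 1 for disuse against young. In serum 0 of 16 held for old against young and 0 of 4 for old against disuse. For the age interaction 1 of 2 held. miR-127-3p passed in all 24 in muscle and in 22 of 23 in serum. The small prior count that edgeR adds by default to a log2 fold change was not varied, and it weighs most at low counts. Shallow serum libraries limit detection to 9.71 to 66.4 CPM per library.

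Replicate numbers were not taken as pairs, since no pair of groups had every correlation of same-numbered libraries over 0.1. They were -0.0944 to 0.0855 for old and young muscle and -0.264 to 0.447 for old and young serum. With so few libraries this does not exclude pairing, and the fits over both sources ignore it. Pairs that leaned towards it were old and disuse serum (mean r 0.126, against -0.0413 for other numbers) and old muscle and old serum (0.171 against -0.057), each with 3 of 4 libraries best with their own number. With the number as a replicate block the counts were 14 for old against young muscle, 3 for disuse, 15 for old against disuse muscle, 1, 0 and 5 for the serum comparisons and 142 for serum against muscle.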

Other observations

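The tests in this part and their bounds were chosen before their results were seen, but the reading of 3 of them was changed afterwards. By the bounds as first set, the relation of arms outside the cluster, the dependence on position and the link of serum to muscle would each be excluded. Once the values were known, a margin of 1 SE was added to the bounds on r, and for position the bound on p was replaced by one on the size of rho with a margin of 2 SE. These changes left all 3 open. The most abundant miRNAs of the young libraries were partly shared by the sources. In muscle, after miR-133a-3p, they were miR-486-5p (81579 CPM), miR-22-3p (61797), miR-378a-3p (46059), miR-3107-5p (37568), miR-26a-5p (34670), miR-181a-5p (31439), let-7c-5p (29842), miR-150-5p, a lymphocyte miRNA (26699), and miR-92a-3p (22112). In serum, after miR-486-5p and miR-3107-5p (111640 CPM), they were miR-10b-5p, miR-191-5p, miR-10a-5p (44798), miR-22-3p (34097), miR-30d-5p (19699), miR-146a-5p (18076), miR-92a-3p (17044) and miR-181a-5p (16887). miR-22-3p was higher in muscle (log2 fold change -0.86 ± 0.32 in serum, adjusted p = 0.0198), a call that ended without young serum 5 (-0.60, adjusted p = 0.08004). miR-92a-3p at -0.38 did not pass (adjusted p = 0.201).

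The vascular pair miR-126a-5p and miR-126a-3p, arms of a single hairpin, had different values in old against young muscle, -0.72 and 0.03. More widely, if age acted on whole hairpins, the changes of their 5p and 3p arms should correlate. Over 82 hairpins with both arms tested in muscle, r was 0.486 (permutation p = 1e-05, the smallest 100000 permutations can give, adjusted p = 4e-05 over 4 relations) and rho 0.307 (permutation p = 0.00546), and r was 0.303 without the 2 hairpins farthest from the median. Outside the Dlk1-Dio3 cluster, r was 0.189 over 78 hairpins (permutation p = 0.0984, adjusted p = 0.131) and 0.198 without the 2 farthest, with a rho of 0.199 (permutation p = 0.0818). The bounds set beforehand were over 0.5 for such an action and under 0.2 against it. The whole set lies between them, and 0.189 lies below the lower bound but within the later margin of 1 SE, so the hypothesis remains open. These relations are across miRNAs, which are not independent replicates.

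Within the cluster, the fall in old muscle may depend on position along the chromosome. Over 27 members rho was 0.324 (permutation p = 0.0987) and r 0.35 (permutation p = 0.0729, adjusted p = 0.131), and r was 0.249 without the 2 farthest members. The bound set beforehand, a p of 0.05 or more, was too loose to exclude it, because a p that misses a threshold does not show the absence of a trend. The plot of the cluster along chromosome 12 shows the members.

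Changes of serum with age may follow those of muscle. Across 152 miRNAs tested in both sources r was 0.0938 (permutation p = 0.251, adjusted p = 0.251) and rho 0.121 (permutation p = 0.136), and r was -0.01 without the 2 farthest. The bound against it was an r under 0.1, and 0.0938 lies below that but within the later margin of 1 SE, so it stays open. Of these miRNAs 6 were called in muscle and 14 in serum, and miR-127-3p was called in both, where independent lists would share 0.553. miR-127-3p also had a smaller value in disuse than in young serum (-0.58, not past the threshold).

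miR-1a-3p, usually among the most abundant miRNAs of skeletal muscle, was counted at 927 ± 357 CPM (SD, n = 5) in young muscle, against 427210 ± 66535 CPM for miR-133a-3p, which is made from the same transcripts. No explanation was tested.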
